A study of Mus musculus with 15 samples.

How the data were processed

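The 5 peak lists come from ChIP-seq of wild type, CD69-negative CD4+CD8+ thymocytes: 1 CTCF, 2 Rad21 and 2 H3K27ac libraries. The 8 Hi-C samples of wild type, CTCF knockout and CTCF with Rad21 double knockout cells and the 2 input samples were not analysed here. Groups and replicate numbers were taken from the labels.

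The lists are in the narrow peak format for CTCF and Rad21 and the broad peak format for H3K27ac, 1 per library, on genome build mm9 per the submitters' processing notes. The same notes name CASAVA 1.82 and 1.84, Bowtie 1.0.0 and MACS2 2.1.0 for the series, beside Bowtie2 2.3.2, HiC-Pro 2.7.8 and Juicer 0.7.5, without saying which was used for what. The thresholds and the control of the peak calls are not given in the sources used here. Each peak has a fold enrichment, which is a ratio over local background computed by the authors' caller and was used within a list to describe, rank or filter peaks and to compare Rad21 peaks with and without CTCF. Between lists it was compared only as Spearman correlations of the replicates of a target. Each has −log10 p and −log10 q values, deposited as the caller wrote them, and a score, which the authors' files give as a multiple of −log10 q (of −log10 p for CTCF) and which was not used. The narrow lists add the summit as its distance from the peak start in bp, as deposited. The smallest −log10 q was 1.31 and 1.32 in the Rad21 lists, 0.188 and 0.00455 in the H3K27ac lists and 0 in the CTCF list, whose smallest −log10 p was 1.72. A peak list carries no read counts, so the depth and the precision it would give are unknown.

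Peaks on chromosomes 1 to 19 and X were kept, and entries with the same coordinates, which are several summits of a peak, were counted once at the highest fold. This left 35345 CTCF peaks, 38430 and 48462 Rad21 peaks and 38700 and 24765 H3K27ac peaks, with median widths of 200, 228, 237, 1076 and 733 bp. Peaks of both replicates were merged, and a merged region with a peak of each was called shared, which gave 30959 Rad21 and 16230 H3K27ac regions. An overlap needed at least 1 bp. Chance was measured by 1000 circular shifts of a list along each chromosome, between the first and last peak of all lists, and intervals by 1000 bootstrap draws of 10-Mb blocks. Chance shares at promoters by class of region came from 200 shifts. The smallest p of 1000 shifts is 0.000999 one-sided and 0.002 two-sided. These tests concern the placement of peaks in these libraries and not a spread between animals.

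H3K27ac regions within 12000 bp were stitched into clusters, and a cluster was isolated when its neighbours on both sides were at least 200000 bp away. The 40 clusters at the ends of chromosomes were left out. Isolated and other clusters were compared with 10000 permutations of the label within 5 classes of width or within chromosomes, with 0.0002 as the smallest two-sided p. CTCF density was counted within 500000 bp on either side.

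Gene models were those of GENCODE vM1 on NCBIM37, the assembly that mm9 displays, and no peak ran past the end of a chromosome of that assembly. A promoter was 2000 bp on either side of a TSS of 22342 protein-coding genes. Ptcra, which that release does not class as protein-coding, was added. Lists of marker and pathway genes were compared with all other genes by Fisher's exact test with Benjamini-Hochberg adjustment over 27 tests. Genes that share a promoter region are not independent. The CTCF core consensus CCASYAGRKGGCR was searched on both strands within 50 bp of summits with at most 2 mismatches and set against windows 1000 bp downstream by an exact McNemar test. Some of those p-values were too small to be represented, and only percentages are then given.

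The samples, the comparisons with their tests, the gene lists and the alternative settings were chosen before the data were examined. The alternatives were a −log10 q of at least 5, an overlap of at least 50% of the shorter region, 100 bp on either side of the summit, equal numbers of top peaks, a local shift by 50000 to 500000 bp, autosomes only, each replicate left out, isolation at 100000 or 400000 bp, stitching within 3000 bp, flanks of 200000 bp, promoters of 500 bp and at most 1 mismatch. 5 further alternatives were chosen after seeing the data, among them one that matched Rad21 and H3K27ac lists of the same replicate number, as was a comparison of the threshold in the H3K27ac lists with 200 draws that kept as many H3K27ac peaks at random, or by the q of another peak of the list. The rule for named genes was to give up to 8 genes per list in the order of the list, and to name the 8 isolated clusters with the largest smaller gap, the 8 widest clusters, and the 6 CTCF-free and 4 CTCF-bound Rad21 regions with the best worse-of-both-replicates rank by fold. Values of some single genes that this rule would name are not reported here.

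The scripts were tested on simulated data. With an overlap planted at 30% of 30959 Rad21 regions, 30.3% was recovered where 30.2% was due. Of lists placed without association, 2.5% gave a p below 0.05. A planted height ratio of 2 gave 2.00 over 38430 peaks, and a planted difference of -20 percentage points between 11783 clusters gave -22.4. All of 2000 planted motifs were found on the right strand and position, and 3.6% of random sequences held a match. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.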

Results

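CD4+CD8+ double-positive thymocytes are immature T cells that rearrange the T cell receptor alpha chain, and those without CD69 at the surface have not yet received a selection signal. Cells of this kind from wild type C57BL/6 thymus were profiled by ChIP-seq for CTCF, a sequence-specific DNA-binding protein that holds cohesin in place, for Rad21, a core subunit of the cohesin ring, and for H3K27ac, a histone acetylation of active promoters and enhancers. The series holds 15 samples, of which 5 peak lists were used: 1 for CTCF, 2 for Rad21 and 2 for H3K27ac. Its title concerns loop extrusion by cohesin, and the question open to peak lists is where cohesin lies relative to CTCF sites and to active chromatin. The 8 Hi-C samples and 2 input samples were not analysed here. Peak lists carry no read counts, so the depth of each library is unknown. The labels do not say whether replicates came from separate animals, so the spread between them may be technical.

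Of the replicate 1 peaks a larger share was found again for Rad21 than for H3K27ac, and of the replicate 2 peaks a smaller one. Of 38430 Rad21 peaks in replicate 1, 83.0% overlapped a peak of replicate 2 (95% block bootstrap interval 82.6 to 83.4), and 65.1% of the 48462 peaks of replicate 2 overlapped a peak of replicate 1. For H3K27ac, 42.0% of the 38700 peaks of replicate 1 (interval 40.4 to 43.6) and 74.8% of the 24765 peaks of replicate 2 were matched. Shifted lists gave 1.06% for Rad21 and 2.61% for H3K27ac, and each one-sided permutation p was 0.000999, the smallest that 1000 shifts can give. The Rad21 peaks that were not matched were low: their median fold enrichment was 5.02 in replicate 1 and 5.27 in replicate 2, against 8.93 and 10.8 for matched peaks. Among peaks in the top 25% by height, 99.9% and 99.3% were matched. Across the 30959 shared Rad21 regions the heights of the replicates had a Spearman rho of 0.773, where regions are not independent replicates. The H3K27ac lists covered 63.5 and 26.0 Mb, and heights across the 16230 shared regions had a rho of 0.0642, so H3K27ac heights and q values entered only alternative settings. Restricting all lists to −log10 q of at least 5 lowered the H3K27ac overlap to 13.8%, where as many H3K27ac peaks kept at random gave 12.5% (11.95 to 13.1 in 200 draws).

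Most shared Rad21 regions lay on a CTCF peak. Of 30959 regions, 20400 (65.9%, interval 64.9 to 66.9) overlapped one, where shifted CTCF lists gave 0.822% (one-sided permutation p = 0.000999, the smallest possible). The 4 CTCF-bound regions ranked highest in both replicates were at the promoter of Snx18, a sorting nexin gene (chromosome 13, 114408512 to 114409161, Rad21 folds 95.4 and 104, CTCF fold 22.9), in an intron of Emid1 (chromosome 11, 5014954 to 5015516, 92.5 and 101.3), in intergenic sequence nearest to Fabp5 (chromosome 3, 9947403 to 9948125, 81.0 and 96.0) and in intergenic sequence nearest to Ano6 (chromosome 15, 95556209 to 95556810, 79.8 and 98.7). The share was lower among all peaks of a single replicate, at 52.4% ± 7.29 (SD, n = 2). In the other direction, 58.2% of 35345 CTCF peaks held a shared Rad21 region (interval 57.2 to 59.3), against 0.722% by chance (permutation p = 0.000999, the smallest possible).

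Rad21 at CTCF peaks depended on how high the CTCF peak was. In the lowest of 10 height bins 12.5% of CTCF peaks held a shared Rad21 region, in the fifth 56.7%, and in the highest 94.6%. The low bins were also poor in the CTCF motif, which was present at 21.8% of summits in the lowest bin and 91.2% in the highest. The CTCF list reaches below the usual threshold, since 29.1% of its peaks had q above 0.05. Rad21 was present at 19.6% of those peaks and at 74.1% of the remaining 25048.

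**Figure D1:**
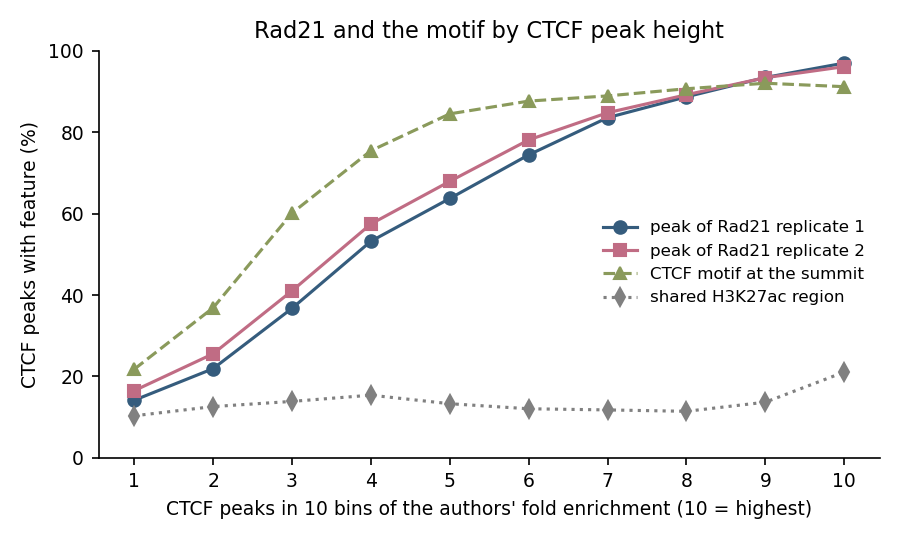
Share of CTCF peaks (%, y axis) that hold a Rad21 peak of each replicate, a CTCF motif at the summit or a shared H3K27ac region, in 10 equal bins of the authors' fold enrichment (x axis, 10 is the highest). The Rad21 share rises from 14.1% and 16.5% in the lowest bin to 97.0% and 96.1% in the highest, and the H3K27ac share stays between 10.3% and 21.1%.

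Rad21 regions without a CTCF peak lay mainly in active chromatin. Of 10559 such regions, 7604 (72.0%, interval 70.9 to 73.0) overlapped a shared H3K27ac region, against 3824 of the 20400 CTCF-bound regions (18.7%, interval 18.1 to 19.4). The difference was 53.3 percentage points, where shifted H3K27ac regions gave at most 1.87 (two-sided permutation p = 0.002, the smallest possible). With single Rad21 replicates the difference was 46.1 ± 3.001 percentage points (SD, n = 2), and with single H3K27ac replicates 53.1 ± 1.98 (SD, n = 2). All shared regions then fell into 16576 with CTCF only (53.5%), 7604 with H3K27ac only (24.6%), 3824 with both (12.4%) and 2955 with neither (9.54%). Among all peaks of replicates 1 and 2 the last class made up 14.3% and 19.98%. CTCF-free regions were at promoters in 39.2% of cases and CTCF-bound regions in 19.3%, where shifts gave 5.02% and 5.01%. Of the CTCF-free regions at H3K27ac, 3840 (50.5%) lay outside promoters. The difference was 34.02 percentage points with −log10 q of at least 5 in the Rad21 and CTCF lists, and 5.34 with that threshold in the H3K27ac lists as well, where as many H3K27ac peaks kept at random gave 4.49 (3.78 to 5.33 in 200 draws).

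**Figure D2:**
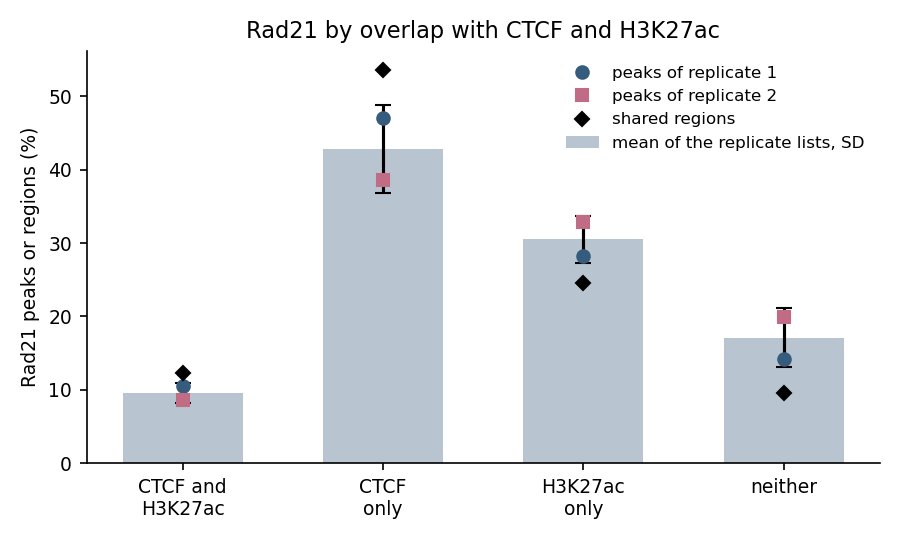
Rad21 peaks or regions (%, y axis) by overlap with CTCF peaks and shared H3K27ac regions (x axis). Bars give the mean of the replicate lists and error bars the SD (n = 2), circles and squares the peaks of replicates 1 and 2, and diamonds the shared regions. Among shared regions 53.5% have CTCF only and 24.6% have H3K27ac only.

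Named by the rank rule, the strongest CTCF-free Rad21 regions included a pair at Tbl1xr1, which encodes a subunit of nuclear receptor corepressor complexes. One lay 139415 bp from the nearest Tbl1xr1 TSS (chromosome 3, 21834330 to 21836159, folds 42.5 and 48.6) and the other at its promoter (21975517 to 21976828, folds 45.2 and 39.6), 451 bp from a CTCF peak. A region at the promoter of Pip4k2a, a phosphoinositide kinase gene (chromosome 2, 18917942 to 18920430, folds 26.99 and 34.8), and one in an intron of Ptpn14, a tyrosine phosphatase gene (chromosome 1, 191654276 to 191655301, folds 26.3 and 34.5), also overlapped H3K27ac. The remaining regions of that rank, nearest to Ube2e3 (chromosome 2, 78799574 to 78800066) and to Lpin1 (chromosome 12, 16237886 to 16238294), were intergenic and had no H3K27ac peak in either replicate.

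The CTCF motif followed the CTCF peaks. It was present at 85.1% and 84.5% of the summits of CTCF-bound regions (replicates 1 and 2), where windows 1000 bp away gave 5.58% and 5.74%. At CTCF-free regions in H3K27ac it was present at 10.2% and 9.74%, above 5.18% and 5.35% in the windows (exact McNemar p = 4.7e-31 and 1.3e-24). CTCF-free regions outside H3K27ac differed from both, with a motif at 53.5% and 53.8% of summits. CTCF peaks with Rad21 had a motif in 85.8% of cases and CTCF peaks without it in 54.9%. Allowing at most 1 mismatch lowered the shares for replicate 1 to 62.3% at CTCF-bound regions, 1.34% at CTCF-free regions in H3K27ac and 29.0% at those outside, with the windows at 1.15%, 0.697% and 0.778%.

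**Figure D3:**
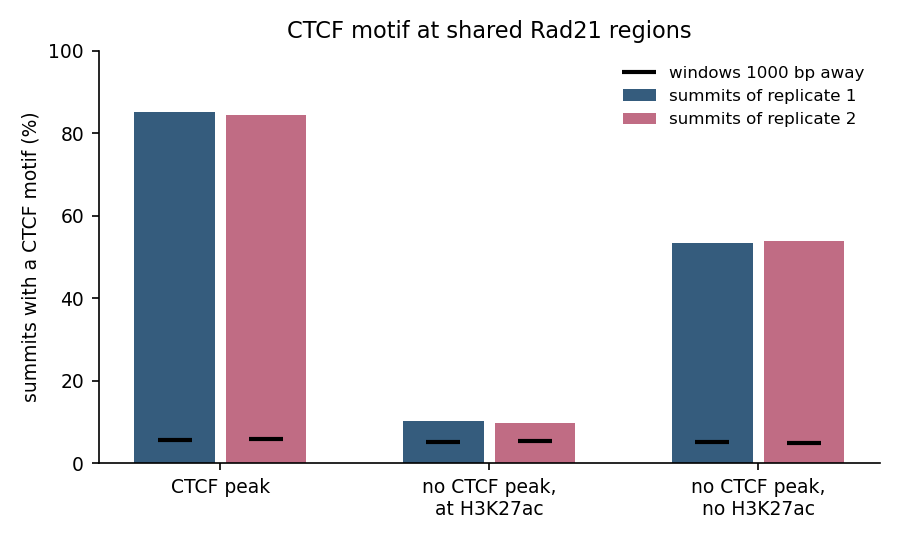
Share of Rad21 summits (%, y axis) with a CTCF core motif of at most 2 mismatches within 50 bp, by class of shared Rad21 region (x axis), with bars for the summits of replicates 1 and 2 and black lines for windows 1000 bp downstream. Regions with a CTCF peak reach 85.1% and 84.5%, regions at H3K27ac without one 10.2% and 9.74%, and regions with neither 53.5% and 53.8%.

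Rad21 peaks were higher on CTCF peaks than elsewhere. The ratio of median fold enrichments was 2.16 in replicate 1 and 2.32 in replicate 2, with a geometric mean of 2.24 (1.16 on the log2 scale). Shifted CTCF lists gave 1.10 on average and at most 1.302 (two-sided permutation p = 0.002 with n = 2 lists, the smallest possible). Among shared regions the median folds in replicate 1 were 13.1 for CTCF only, 11.6 for CTCF with H3K27ac, 5.96 for H3K27ac only and 6.14 for neither.

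About as many shared H3K27ac regions had Rad21 as lacked it. Of 16230 regions, 49.3% held a shared Rad21 region (interval 48.4 to 50.3) and 34.8% a CTCF-free one, against 3.41% and 1.19% by chance (one-sided permutation p = 0.000999 for both, the smallest possible). The even split depends on using shared regions. With Rad21 replicate 1 or 2 alone 56.1% and 69.5% held a Rad21 peak, and with H3K27ac replicate 1 or 2 alone 23.9% and 33.5% of peaks held a shared Rad21 region. The 8 widest stitched clusters spanned 103234 to 203326 bp. They covered Cux1, a homeobox gene (chromosome 5, 136846783 to 137050108, 203326 bp, 13 CTCF-free Rad21 regions), Mad1l1, a spindle checkpoint gene (chromosome 5, 140618344 to 140780192, 11), a stretch with Itgal, which encodes the alpha chain of the integrin LFA-1 (chromosome 7, 134323805 to 134452356, 6), and part of Atp10a (chromosome 7, 65932165 to 66058537, 7). The Cd8a and Cd8b1 coreceptor genes shared a cluster of 115237 bp with 19 CTCF-free Rad21 regions (chromosome 6, 71246788 to 71362024). Rhoh, a GTPase gene of blood cells, lay in one of 110841 bp with 28 (chromosome 5, 66239425 to 66350265), Znrf1, a ubiquitin ligase gene, in one with 18 (chromosome 8, 114060003 to 114168555), and Dad1, which flanks the T cell receptor alpha locus, overlapped one with 3 (chromosome 14, 54756181 to 54859414).

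H3K27ac regions with a CTCF-free Rad21 region were wider. For shared regions the ratio was close to what width alone would give, while single H3K27ac lists exceeded it. Their median was 2703 bp and that of the others 1528.5 bp, a ratio of 1.77, where shifts of the Rad21 regions gave 1.70 (two-sided permutation p = 0.597) and local shifts 1.94 (permutation p = 0.0839). With H3K27ac peaks of a single replicate the ratio was 2.54 for replicate 1, against 1.79 by shifts (permutation p = 0.002, the smallest possible). For replicate 2 it was 2.40 against 1.66 (permutation p = 0.004). The share of H3K27ac peaks at Rad21 was then 23.9% and 33.5% for replicates 1 and 2, and at CTCF-free Rad21 15.9% and 23.7%. With Rad21 replicate 2 alone 58.5% of the shared H3K27ac regions held a CTCF-free Rad21 peak. Rad21 and H3K27ac lists of the same replicate number gave width ratios of 2.40 and 2.33, against 1.86 and 1.70 by shifts (permutation p = 0.002 for each, the smallest possible).

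Isolated H3K27ac clusters, with no other cluster within 200000 bp on either side, held CTCF-free Rad21 less often than the rest. Of 627 isolated clusters 130 (20.7%) held such a region, against 39.8% of the others, a difference of -19.1 percentage points. The shares were 49.1% and 63.9% with Rad21 replicate 2 alone, 8.95% and 24.5% with H3K27ac replicate 1 alone, and 13.5% and 31.6% with H3K27ac replicate 2 alone. Labels permuted among clusters of like width gave -7.62 (two-sided permutation p = 0.0002, the smallest possible). That permutation holds cluster width and not the chromosome or the local density of peaks. Its p-value cannot tell a lack of CTCF-free Rad21 from stretches poor in all marks. The clusters with the widest gaps were at the promoters of 3110007F17Rik (chromosome X, 120216727 to 120217505), Dsel (chromosome 1, 113760904 to 113762067), Wdr44 (chromosome X, 23270157 to 23271546), Rnpc3 (chromosome 3, 113332175 to 113333642), Fancf and Gas2 (chromosome 7, 59116903 to 59118309) and BC067068 and Ccdc59 (chromosome 10, 105278111 to 105279002), in an intergenic stretch nearest to Cntnap5b (chromosome 1, 103798587 to 103801085), and over Tspan14, a tetraspanin gene (chromosome 14, 41736812 to 41780550). The Tspan14 cluster held 3 CTCF-free Rad21 regions, the Rnpc3 cluster 1 and the other 6 none. With −log10 q of at least 5 in all lists the difference turned to 2.46 percentage points (two-sided permutation p = 0.128), where as many H3K27ac peaks kept at random gave -5.56 (-12.4 to -0.241 in 200 draws) and as many kept by the q of another peak -2.96 (-10.7 to 3.81). Among these draws 2.46 had a two-sided permutation p of 0.00995, the smallest possible, and of 0.0498.

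CTCF peaks were also sparse around isolated clusters. The median was 10 peaks per Mb in the 500000 bp on either side (quartiles 6 and 15.5) against 24 around other clusters (quartiles 16 and 34). Permuting labels within chromosomes gave a difference of -1.10 per Mb, and the observed one was -14 (two-sided permutation p = 0.0002, the smallest possible). Isolated clusters lie by definition in stretches poor in H3K27ac clusters, and this permutation does not hold the local density of peaks. The p-value therefore cannot tell a lack of CTCF from stretches poor in all marks. The difference was -9 with −log10 q of at least 5 in the Rad21 and CTCF lists and -3 with that threshold in all lists, where as many H3K27ac peaks kept at random gave -4.41 (-6 to -2 in 200 draws).

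All 18 genes of T cell receptor and coreceptor signalling had a shared H3K27ac and a shared Rad21 region within 2000 bp of a TSS, against 40.8% and 29.7% of other genes (Fisher's exact test, two-sided, adjusted p = 9.0e-07 and 4.4e-09 over 27 tests). Rad21 was at 59.3% of all genes with promoter H3K27ac and at 9.29% of those without. CTCF was present at 4 of the 18, close to 23.7% of other genes (exact test, adjusted p = 1), and the share was 5.56% within 500 bp. Among all genes with promoter H3K27ac, which all 18 had, CTCF was at 39.4%, and the list was not tested against those. Cd3e, a chain of the CD3 complex (chromosome 9, 44806826 to 44817673), had Rad21 folds of 13.1 and 10.0 and no CTCF peak. Cd3d and Cd3g, which are transcribed away from each other, shared Rad21 folds of 24.9 and 12.3 and a low CTCF peak of fold 2.73. Cd247, Cd4, Cd8a, Cd8b1 and Ptcra, which encodes the pre-T cell receptor alpha chain, had Rad21 folds in replicate 1 of 11.5, 12.4, 11.6, 29.1 and 5.58 and no CTCF peak within 2000 bp of a TSS. Of these 5 genes, Cd8b1 had a Rad21 region that reached a CTCF peak farther away.

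Regulators of the double-positive stage gave a like picture. H3K27ac was at 20 of 22 promoters (exact test, adjusted p = 9.8e-06) and Rad21 at 21 (adjusted p = 3.6e-09), while CTCF at 10 did not pass (adjusted p = 0.0575) and was at 27.3% within 500 bp. Rag1 and Rag2, the recombinase genes, had Rad21 folds of 9.07 and 12.3 in replicate 1 and no CTCF peak, as had Tcf7 (10.3), Lef1 (10.8) and Tcf12 (11.3). Bcl11b, a gene of T lineage commitment, had both, with a CTCF fold of 8.43 and Rad21 folds of 34.03 and 63.4, and so had Satb1, a chromatin organiser gene (9.88, with 23.3 and 26.3). The genes of the list without H3K27ac were Runx3 and Zbtb7b, which direct the CD8 and CD4 lineages at a later stage and were singled out after their values were seen. Runx3 had CTCF (fold 19.1) and Rad21 (folds 47.2 and 32.2), and Zbtb7b had none of the marks.

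**Figure D4:**
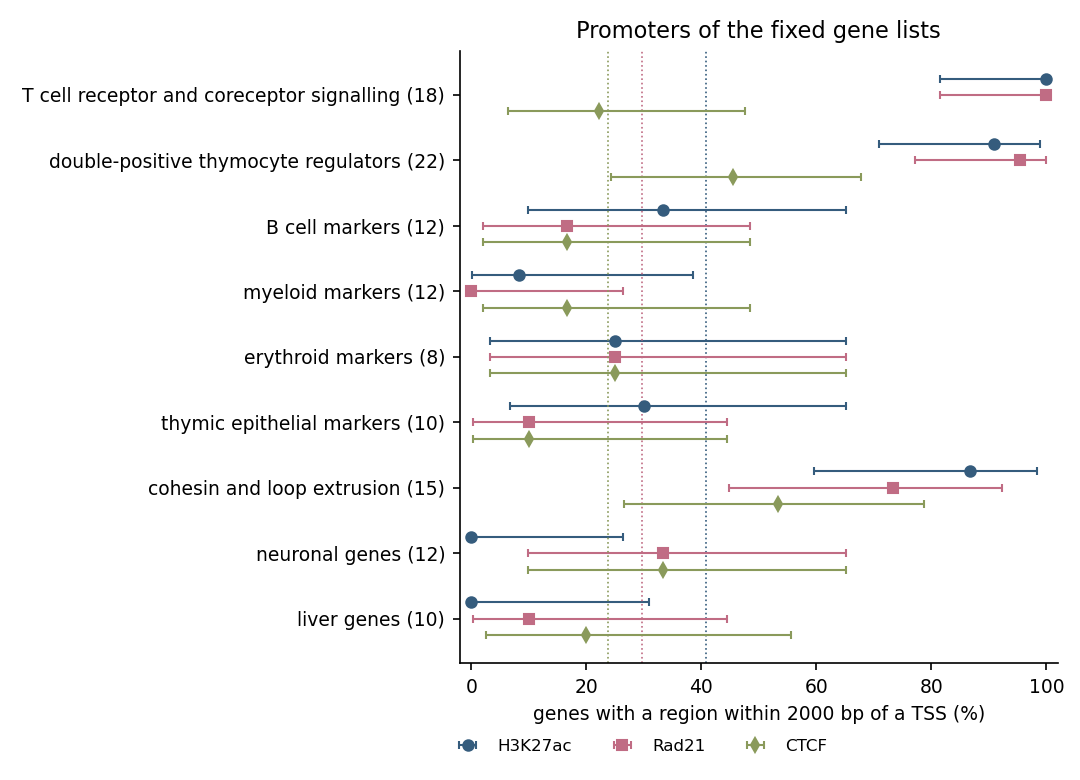
Genes of each fixed list (number of genes in brackets) with a shared H3K27ac region, a shared Rad21 region or a CTCF peak within 2000 bp of a TSS (%, x axis), with exact 95% binomial intervals. Dotted lines give the share among other genes, 40.8% for H3K27ac, 29.7% for Rad21 and 23.7% for CTCF. T cell receptor genes stand at 100% for H3K27ac and Rad21, and neuronal and liver genes at 0% for H3K27ac.

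Genes of other cell types mostly lacked H3K27ac at their promoters. None of 12 neuronal genes had it (exact test, adjusted p = 0.00856), among them Neurod1, Snap25, Syt1, Gria2 and Grin1, yet Rbfox3, Neurog2 and Gad1 had CTCF and Rad21 together, with CTCF folds of 16.2, 17.1 and 9.01. CTCF and Rad21 were each at 4 of the 12 neuronal genes, which did not pass (exact test, adjusted p = 0.77 and 0.906). None of 10 liver genes had it (exact test, adjusted p = 0.0244), among them Alb, Ttr, Cyp7a1, Fgb and Tat, while Apoa1 had CTCF and Rad21 and Apob had CTCF alone. Within 500 bp no gene of these 2 lists had shared Rad21 or CTCF. Of 12 myeloid genes only Spi1 (annotated as Sfpi1) had H3K27ac (exact test, adjusted p = 0.0783, with 0.0483 for H3K27ac replicate 2 alone and 0.178 for replicate 1 alone) and none had shared Rad21 (adjusted p = 0.0575). Csf1r, Itgam, Mpo, Elane and Cd14 lacked all 3 shared marks. Lyz2 and Cebpa had CTCF and neither shared mark, with a Rad21 peak at Cebpa in replicate 1 only (fold 5.40). H3K27ac was at 4 of 12 B cell genes (exact test, adjusted p = 0.906), at 2 of 8 erythroid genes (adjusted p = 0.77) and at 3 of 10 thymic epithelial genes (Aire, Cldn4 and Ly75, adjusted p = 0.77), where Ly75 was named after its values were seen. Within 500 bp these shares were 16.7%, 12.5% and 30%. Pax5, Ebf1, Gata1, Foxn1, Krt5 and Krt8 had none of the marks.

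Cohesin genes carried all marks more often than other genes. H3K27ac was at 13 of 15 promoters (exact test, adjusted p = 0.00194), Rad21 at 11 (adjusted p = 0.00276) and CTCF at 8 (adjusted p = 0.0376). Of all genes with promoter H3K27ac, 59.3% had Rad21 and 39.4% had CTCF. The list was not tested against those, so promoter activity may account for part of the excess. Smc3, Stag1, Stag2 and Nipbl, which encodes the cohesin loader, had CTCF folds of 8.43, 26.998, 20.7 and 17.4 with Rad21 folds in replicate 1 of 18.6, 31.3, 31.0 and 24.96. Mau2 and Wapl (annotated as Wapal), the partner of the loader and the release factor, had Rad21 without CTCF. Smc1a and Rad21 itself had H3K27ac and no shared Rad21 region. Rad21 peaks were still listed there, at the Rad21 gene in both replicates (folds 4.59 and 6.44) and at Smc1a in replicate 2 (fold 5.27). Among all 22342 protein-coding genes, 37.5% of the 9132 with promoter H3K27ac had a CTCF-free Rad21 region there, against 1.92% of the others.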

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

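The tests of missed CTCF sites, of unlike replicate lists and of stricter thresholds in the Rad21 and CTCF lists or in the Rad21 lists alone were chosen after seeing the data, and the last only after the one before it had left the point open.

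Peaks outside the chromosomes compared were found in a pair of libraries. H3K27ac replicate 1 has 4 peaks on chromosome Y, with folds of 2.24 to 3.70, and the other lists have none there. Rad21 replicate 2 has 15 peaks on the mitochondrial genome, between positions 44 and 16180 and with folds of 1.72 to 4.55, and the other lists have none there.

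Of the CTCF-free Rad21 regions 72.0% overlapped H3K27ac. CTCF sites with a motif that the peak caller missed are argued against as the whole cause. The excess of motifs over control windows was at most 6.29% of that at CTCF-bound regions. Missed sites without a motif stay open, as only 21.8% of CTCF summits in the lowest height bin held one. Rad21 peaks near the detection limit are argued against at most as the whole cause. With −log10 q of at least 5 in the Rad21 lists alone the share was 69.6% of 5702 regions. That threshold left 5702 CTCF-free regions of 10559 but 18335 CTCF-bound ones of 20400, so the CTCF-free class lost more. CTCF-free regions at and outside H3K27ac had like median folds in replicate 1 (5.96 and 6.14). A threshold on height drops both alike, so the share had little room to move and decides little. The first version of this test, with that threshold in the CTCF list too, gave 49.99% of 10067 regions and decided nothing by itself, and there the share of Rad21 regions at CTCF went from 76.3% to 58.1%, so regions with a weak CTCF peak entered the CTCF-free class. Enrichment at active chromatin common to several antibodies may account for part of the pattern, as CTCF peaks without a motif were in 11.4% of H3K27ac regions and CTCF-free Rad21 in 34.8%, and no biological explanation was tested.

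Rad21 regions with neither CTCF nor H3K27ac had a motif at 53.5% and 53.8% of summits. CTCF sites missed by the peak caller are a candidate explanation: the excess of motifs was at least 60.7% of that at CTCF-bound regions in both replicates. Part of the class stays without an account, and no biological explanation was tested.

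H3K27ac heights in shared regions did not follow each other between replicates, with a Spearman rho of 0.0642 across regions. Peak lists of unlike replicates are argued against for the widest peaks only. Of the widest 25% of replicate 2 peaks 98.1% lay on a replicate 1 peak, as did 76.8% in the other direction. Of the narrowest 25%, 49.96% in replicate 2 and 14.96% in replicate 1 were matched, so unlike lists stay open there. Height columns that do not describe the listed peak may explain why the heights did not follow each other. Widths had a rho of 0.634 between replicates, whereas a peak's height had a rho of 0.0573 and 0.0861 with its own width. With the height of the next peak along the chromosome the rho was 0.663 and 0.592. In the Rad21 lists those values were 0.596 and 0.610 for the own width and 0.0363 and 0.0314 for the next peak. No biological explanation was tested.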

How the results depend on the processing

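The 4 thresholds that treat the lists differently (Rad21 and CTCF only, Rad21 only, H3K27ac by width, CTCF by q), the draws of H3K27ac peaks and the replicate block were chosen after seeing the data. Of 230 alternatives over 50 results, 217 kept the direction and the side of the 0.05 threshold, including all that concern Rad21 at CTCF, CTCF at Rad21 and the H3K27ac share of CTCF-free Rad21. With −log10 q of at least 5 in all lists the deficit of CTCF-free Rad21 at isolated clusters reversed to 2.46 percentage points (permutation p = 0.128), with 1592 clusters left of 11783. The same threshold in the Rad21 and CTCF lists only gave -16.7, in the Rad21 lists only -13.7, and the wider 50% of each H3K27ac list -16.7. In the H3K27ac lists −log10 q had a Spearman rho across peaks of 0.0706 and 0.104 with the width of its own peak and of 0.738 and 0.662 with the q of the next peak, so this threshold may drop peaks with little regard to their strength. As many H3K27ac peaks kept at random gave -5.56 (-12.4 to -0.241 in 200 draws, two-sided permutation p = 0.00995, the smallest possible) and peaks kept by the q of another peak -2.96 (-10.7 to 3.81, permutation p = 0.0498). The value 2.46 lay above all random draws, and its cause was not tested. The width ratio of H3K27ac regions passed the threshold when either H3K27ac replicate was left out, and over all replicates left out in turn it ranged from 1.60 to 2.54, with 2.40 and 2.54 past the threshold. Without passing it, the ratio reversed to below its chance value with either Rad21 replicate left out (1.60 against 1.69, and 1.68 against 1.72), an overlap of 50% (1.83 against 1.86), local shifts (1.77 against 1.94) and the wider 50% of each H3K27ac list (1.505 against 1.54). The cause was not tested. Within 500 bp of a TSS the shares reversed to 0% for Rad21 at neuronal genes (24.3% of other genes), 0% for CTCF at neuronal genes (15.3%) and 0% for CTCF at erythroid genes (15.3%), none past the threshold, and the cause was not tested. The H3K27ac share of myeloid promoters passed without H3K27ac replicate 1, at an unchanged 8.33%, and was 16.7% without replicate 2, and the cause was not tested.

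Several values moved while the call held. With −log10 q of at least 5 in all lists the H3K27ac overlap of replicates was 13.8%, the share of CTCF-free Rad21 at H3K27ac 7.30%, and the difference between classes 5.34 percentage points, at 1868 shared H3K27ac regions. Peaks kept at random gave 12.5% (at most 13.1), 6.29% (at most 7.23) and 4.49 (at most 5.33), and peaks kept by the q of another peak at most 12.8%, 6.20% and 4.57, so the values lay above all draws (permutation p = 0.00995 for each, the smallest possible) and far nearer to them than to the values with all peaks. Rad21 at CTCF was 47.2% to 57.5% and H3K27ac at Rad21 23.9% to 69.5% when a replicate was left out. CTCF peaks with q of 0.05 or less gave 59.7% of Rad21 at CTCF, 74.1% of CTCF at Rad21 and a difference of 49.7 percentage points. Rad21 and H3K27ac lists of the same number, which the labels do not say share an animal, were matched as a replicate block and averaged (n = 2 pairs): CTCF-free Rad21 at H3K27ac was 63.8%, the difference between classes 45.3 percentage points, H3K27ac at Rad21 37.3% and the difference at isolated clusters -17.4. The width ratio was 2.37 and passed the threshold (permutation p = 0.002, the smallest possible), as with single H3K27ac lists, and the block changed no other call. Depth limits all lists in an unknown way, since no read counts are given, and the absence of a peak is not the absence of binding.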

Other observations

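The ranking of clusters, the comparison of chromosomes and the use of the interval to read the test of motif orientation were chosen after seeing the data. Clusters of H3K27ac were ranked by the number of CTCF-free Rad21 regions they hold. The Rhoh cluster came first with 28, followed by the Cd8a and Cd8b1 cluster with 19. The Znrf1 cluster and a cluster with Tcf7, a transcription factor gene of T cell development (chromosome 11, 52065010 to 52160000), had 18 each. A cluster of 82687 bp without a TSS (chromosome 16, 10663411 to 10746097) had 17, and one with Sept9 (chromosome 11, 117151985 to 117213331) had 16.

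Of the chromosomes compared, X had the fewest peaks of each mark per Mb. It had 3.97 shared Rad21 regions per Mb, where the autosomes had 9.004 to 22.2, and 2.14 shared H3K27ac regions per Mb against 4.77 to 11.1. CTCF stood at 7.41 peaks per Mb against 10.7 to 23.0, while annotated TSS stood at 12.2 per Mb against 11.04 to 32.4. The share of Rad21 regions at CTCF was 69.4% on X and 60.7% to 70.0% on autosomes.

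The bounds of both hypotheses that follow were set before their values were seen. The first was that Rad21 accumulates on the 3′ side of the CTCF motif. At CTCF peaks with a motif and Rad21, the Rad21 summit was placed against 17645 motifs in replicate 2 and 17652 in replicate 1. Of the summits off the motif centre, 73.5% in replicate 2 and 75.5% in replicate 1 lay 3′ of it. The median offset of all summits was 9 bp in both. CTCF summits at the same motifs had a median offset of -2 bp, and 41.4% of those off the centre lay on the 3′ side. The values are consistent with the hypothesis in both replicates, and other causes of the offset were not tested.

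The second hypothesis was that the CTCF motifs nearest to isolated H3K27ac clusters point towards the cluster. Only motifs at CTCF peaks with a shared Rad21 region were used. Of 1157 motif sides 54.1% pointed towards the cluster (exact 95% interval 51.2 to 57.0, exact binomial p = 0.0057). A motif between neighbouring clusters could count for each, as towards one and away from the other. Motif sides are therefore not all independent, and the p-value and interval are approximate. The share of 54.1% is under the 55% set for the hypothesis and inside the range, up to 55%, set beforehand as going against it. By those bounds the hypothesis is argued against. The interval reaches past 55%, and reading the test by its interval, chosen after the value was seen, leaves the hypothesis open. Other clusters had 54.1% of 14439 motif sides, so any lean towards the cluster may not be special to isolated clusters.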
